A study of Drosophila melanogaster with 8 samples.

How the data were processed

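Transcript levels were measured in adult heads of Drosophila melanogaster, males and females together, on 8 single-colour Affymetrix arrays with biotin-labelled cRNA. The arrays fall into 4 groups of 2. Control flies were of the w1118 strain, which carries neither the driver nor a transgene. The other 3 groups carried the heat-inducible driver Hsp-GAL4 and a UAS transgene for Eyes absent (EYA), either wild type, with the D493N mutation or with the E728Q mutation. Every group spent 1 h at 37 C and then 3 h at 25 C before the heads were collected. Per the labels, RNA came from 200 heads in 4 lots of 50, and 2 µg was taken for labelling. The labels do not say whether the 2 samples of a group came from separate fly cultures, so p-values measure the spread between these samples, which can be technical.

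The deposited values are intensity values on a linear scale, with 1 value per probe set and array, and the median of each array is 100. GCOS, the Affymetrix operating software, is named in the submitters' processing notes. Its version, the background correction and the summary method are not given in the sources used here. All values are whole multiples of their array's smallest value within 0.01 of a step. Of 18952 probe sets, the 183 Affymetrix control probe sets were left out of the tests, and the controls for transcript ends were read only as a measure of RNA quality. The mean signal between the percentiles 2 and 98 ranged from 597.6 to 663.7 across the arrays. That spread of 11.1% was above the tolerance of 5%, so the arrays were quantile normalized. A pseudocount of 17.5, the 25th percentile of all deposited values, was added before log2 transformation. The 60% of probe sets with the highest mean over the 8 arrays were tested, 11261 of 18769, and the lowest mean among them was 38.1. Group means and SDs printed as signal are of the deposited values, and log2 fold changes are of the normalized values. With 2 arrays per group, the number of arrays limits the precision.

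All 8 arrays entered a single linear model with a coefficient per group in limma 3.58.1 under R 4.3.3. It had 4 residual and 4.75 prior degrees of freedom, with the prior variance following the mean level. There were 7 comparisons, namely each EYA group against control, each pair of EYA groups, and the mean of the 3 EYA groups against control. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. Replicate numbers were not in the model, because no protocol says that they mark a shared day. Probe sets called in all 3 comparisons against control were counted beside the overlap of independent lists. Correlations and covariances of the fold changes were set beside 100 simulations of unchanged groups that share the same controls. Probe sets called in the wild-type group against control and against both mutants in the same direction were counted as wild-type-specific.

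Gene symbols came from the array annotation, which gives exactly 1 symbol for 13647 probe sets, several for 402 and none for the 4903 probe sets it leaves out. Current symbols were taken by gene identifier for 13544 of the 13647 from an annotation of the assembly Release 6 plus ISO1 MT. That annotation was used only for names and for which genes neighbour each other. Where a gene had several probe sets, the one of highest mean stood for it, which gave 8661 genes. The genes named are, in each direction, the 12 of largest change against control and the 5 of largest change between transgenes. They had to be called, with no overlap between the 2 values of the groups compared, and to have 1 symbol. Also named are eya, up to 4 called members of each gene list, and eye specification genes whether called or not. Any other gene in the text is said to have been chosen after its values were seen. No probe set with white as its only symbol was found, so white was not used here.

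The gene lists were eye specification, phototransduction, eye pigment, heat-shock chaperones, ER chaperones, antimicrobial and immune recognition genes, Turandot stress genes, cell cycle, apoptosis, EGF receptor and Ras signalling, Notch signalling, circadian clock, detoxification enzymes, odorant-binding and antennal genes, ribosomal proteins, the mitochondrial respiratory chain, the proteasome, and lipid and carbohydrate metabolism. Markers of neurons, glia, muscle, fat body, female germline, testis and accessory gland, midgut and photoreceptors made up the rest of the 26 lists. The comparisons, the tests, the rule for named genes, the lists and the alternatives were fixed before the data were examined, with the exceptions named below. Lists with at least 5 measured genes, 25 of the 26, were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes. Adjustment was over the lists of a comparison. Each call was repeated with a correlation estimated from the data. That setting called 0 lists in any comparison (lowest adjusted p = 0.856), so a call lost under it does not tell the lists apart. Member counts are given from the adjustment over all probe sets and adjusted over the list alone.

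The alternatives were a pseudocount of 1 or of 100, no filter, a filter that keeps 40%, deposited values without quantile normalization, a common median, only the arrays of the groups compared, no trend in the prior variance, a replicate block, and each array left out in turn. For the lists they also included an estimated correlation, limma's fry, and the mean of a gene's probe sets. A test without the genes of a chromosomal run was added after seeing the data. That run was noticed by inspection and then scanned in windows of 15 neighbouring genes against 200 permutations of gene order. Lists were also compared with 10000 random lists of genes matched on mean level within 50 ranks on each side.

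The test was checked on simulated data for wild-type EYA against control with 11261 probe sets, 200 of them changed, in 20 simulations. It recovered 55.05% of changes of 1.5-fold, 80.54% of changes of 2-fold and 97.07% of changes of 4-fold, and 5.95% of its calls were false. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.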

Results

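The series asks which transcripts respond to Eyes absent (EYA), a transcriptional coactivator of eye development that is also a protein phosphatase. Head RNA was profiled in 4 groups of 2 arrays: control flies, and flies with a heat-induced transgene for wild-type EYA, for EYA D493N, which has reduced phosphatase activity, or for EYA E728Q, which has little if any. The median signal of each array was 100. Replicates correlated across the 11261 tested probe sets with r from 0.981 in the D493N group to 0.991 in the wild-type group, where probe sets are not independent replicates. The SD of the log2 difference between replicates was 0.28 in control, 0.28 with wild-type EYA, 0.39 with D493N and 0.32 with E728Q. The ratio of 3' to 5' signal for the actin gene Act5C, a measure of RNA integrity, was 4.15 and 4.29 in control, 4.28 and 4.35 with wild-type EYA, 5.63 and 6.26 with D493N, and 4.84 and 5.11 with E728Q. D493N replicate 1 also stood apart in the 18S rRNA controls. Its 5' signal was 5619, against at most 2196 on the other arrays, and its 3' signal 11249, against at most 5524. Whether this bears on results that depend on that array was not tested.

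The probe set for eya gave no uniform increase in the transgenic flies. Its signals were 991 and 918 in control, 916 and 915 with wild-type EYA, 1240 and 1554 with D493N, and 1386 and 1140 with E728Q. The log2 fold change against control was -0.04 (adjusted p = 0.855) for wild-type EYA, 0.46 (adjusted p = 0.0234) for D493N and 0.35 (adjusted p = 0.0707) for E728Q. The D493N call was lost without control replicate 1 (adjusted p = 0.102), control replicate 2 (0.107) or D493N replicate 2 (0.0734), and the adjusted p reached at most 0.107 over the alternatives. Whether this probe set lies in the transgene's sequence is not given in the sources used here, so its values do not test whether the transgenes were expressed.

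Wild-type EYA against control asks which transcripts differ when EYA is overexpressed. CG2444 had the largest increase, from a signal of 120.5 ± 40.05 (SD, n = 2) in control to 21195 ± 1645 (SD, n = 2), a log2 fold change of 7.41 (SE 0.15, adjusted p = 7.66e-08). Large increases were also found for sad, a cytochrome P450 of ecdysone synthesis (4.45), the receptor gene mthl8 (4.31), the extracellular matrix gene prc (4.28), slam, which acts in the cellularizing embryo (4.15), the peptidoglycan amidase gene PGRP-SC2 (4.15) and the glutathione transferase gene GstD9 (3.94). CG14949, CG3706, CG3770, CG12105 and Eip63E rose by 3.80 to 4.54 on the log2 scale. The largest decrease was in phu, from 6271 ± 646 to 222 ± 50.3 (SD, n = 2 each), a log2 fold change of -4.65 (SE 0.22, adjusted p = 3.22e-06). Nmdmc, an enzyme of folate metabolism, and Prat2 and Gart, enzymes of purine synthesis, had log2 fold changes of -3.03, -2.93 and -2.82, and AkhR, the receptor for adipokinetic hormone, -2.78. CG5966, CG10513, CG6067, CG13315, Obp99a, CG32437 and NimC4 also fell, with values from -4.45 to -2.72. Where signals of a group lie near or under the pseudocount, as for sad (7.06) and mthl8 (5.53) in control, the size and rank of the change depend on it, with log2 fold changes over the alternatives of 2.53 to 6.05 for sad, 2.35 to 6.11 for mthl8, 2.35 to 5.49 for CG3706 and -3.73 to -1.39 for CG32437.

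With wild-type EYA, camera at its preset correlation called the immune list higher and the detoxification and proteasome lists lower, calls that were lost with an estimated correlation (adjusted p = 0.942 each) and with fry (0.0807, 0.101 and 0.101). Of 20 immune genes 7 rose and 2 fell (9 and 4 adjusted over the list alone), with PGRP-SC2 at 4.15, pirk, a negative regulator of the Imd pathway, at 1.68, GNBP3 at 1.16 and PGRP-SB1 at -1.65. The immune list had adjusted p = 0.0408, and adjusted p = 0.942 with an estimated correlation. Of 44 detoxification genes 7 rose and 23 fell (9 and 26 adjusted over the list alone), with GstD9 at 3.94, Cyp6a23 at 2.74, Cyp4g1 at -2.45 and Ugt35C1 at -2.23. The detoxification list had adjusted p = 0.0116, and adjusted p = 0.942 with an estimated correlation. Of 26 proteasome genes 0 rose and 6 fell (0 and 7 adjusted over the list alone), with Rpn11 at -0.38 and Rpt5 at -0.34. The proteasome list had adjusted p = 0.0116, and adjusted p = 0.942 with an estimated correlation. Without control replicate 1 the calls of Rpn11 (adjusted p = 0.102) and Rpt5 (0.0763) were lost. Lists called by fry alone were eye pigment genes (adjusted p = 0.0391) and lipid and carbohydrate metabolism (0.0478), both lower, and the clock (0.00794), higher. In all, 1284 probe sets were higher and 1232 lower of 11261, and 685 of these differed at least 2-fold. The count of 2516 became 1409 without control replicate 1, 1497 without control replicate 2, 1421 without wild-type replicate 1 and 1468 without wild-type replicate 2. In such a fit the lone array is assumed to vary like the other groups. The immune call was lost without control replicate 2 (adjusted p = 0.0756) or wild-type replicate 2 (0.0733) and with deposited values (0.064), with a range over the alternatives of 0.0111 to 0.942. The proteasome call was lost without control replicate 1 (adjusted p = 0.0985) or wild-type replicate 1 (0.0736), with a range of 0.00115 to 0.942.

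**Figure D1:**
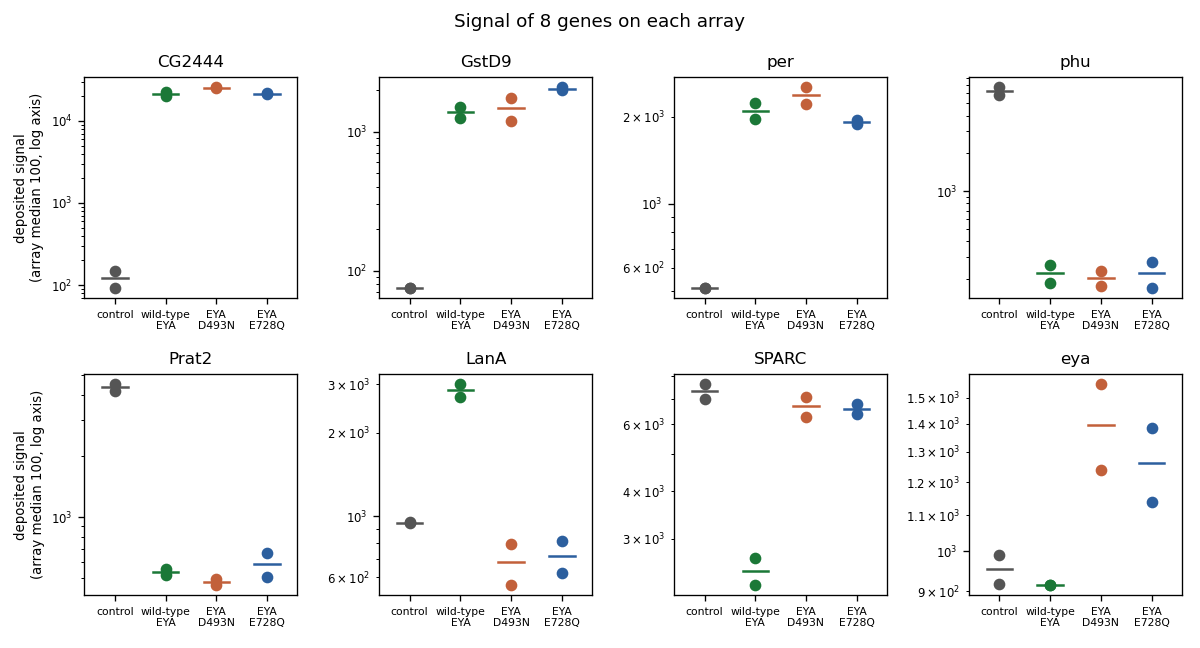
Deposited signal (array median 100, log axis with its own range in each panel) of 8 genes on each of the 8 arrays, with points for arrays and a bar for the mean of the 2 arrays of a group. CG2444, GstD9 and per are higher and phu and Prat2 lower on all 6 EYA arrays than on both control arrays, while LanA is highest and SPARC lowest with wild-type EYA.

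EYA D493N against control asks the same of a transgene with reduced phosphatase activity. CG2444 again had the largest increase, to a signal of 25319 ± 488 (SD, n = 2), with a log2 fold change of 7.44 (SE 0.15, adjusted p = 5.44e-08). The genes mthl8 (4.94), sad (4.22), slam (4.22), GstD9 (3.93), prc (3.87), PGRP-SC2 (3.75), the peptidase genes Nepl4 (3.95) and Ance-4 (3.85), and CG3706, CG14949 and CG3770 (4.23 to 4.64) rose as well. Decreases were largest for phu (-4.79), CG34217 (-4.03), CG13315 (-3.98), CG5966 (-3.57) and the UDP-glycosyltransferase gene Ugt35C1 (-3.51). CG10513, CG6067, Prat2, CG32437, CG15096, Cpr97Eb and Obp99a also fell, with values from -3.45 to -2.82. Low signals again left the size and rank of some changes to the pseudocount, with ranges over the alternatives of 2.90 to 6.76 for mthl8, 2.34 to 5.81 for sad, -6.14 to -2.05 for CG34217 and -5.01 to -1.49 for CG32437. Cpr97Eb had signals of 154 and 1173 on the D493N arrays, and its log2 fold change was -1.50 without D493N replicate 1 and -4.24 without D493N replicate 2. The call of the cuticle protein gene Cpr97Eb was lost without control replicate 1 (adjusted p = 0.0747) or control replicate 2 (0.0616), the highest values over its alternatives.

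Nearly all measured proteasome genes fell with D493N. Of 26, 24 fell and 0 rose (24 and 0 adjusted over the list alone), with Rpn11 at -0.84, Rpt2 at -0.67, Rpt5 at -0.64 and Prosalpha4 at -0.60. The proteasome list had adjusted p = 1.63e-09, and adjusted p = 0.977 with an estimated correlation. These arrays also had the highest Act5C ratios of 3' to 5' signal, 5.63 and 6.26 against 4.15 and 4.29 in control. Of 44 detoxification genes 8 rose and 21 fell (8 and 25 adjusted over the list alone), with Ugt35C1 at -3.51 and Cyp6g1 at -2.25 (adjusted p = 0.00395, and adjusted p = 0.977 with an estimated correlation). Of 11 heat-shock chaperones 6 rose and 0 fell (8 and 0 adjusted over the list alone), with DnaJ-1 at 0.94 and Hsp27 at 0.53. Of 14 ER chaperones 6 rose and 0 fell (7 and 0 adjusted over the list alone), with Sil1 at 0.64 and PEK at 0.56. Both chaperone lists had adjusted p = 0.0233, and adjusted p = 0.977 with an estimated correlation. Of 17 clock genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), among them per at 2.09, Pdp1 at 1.12 and vri at 0.98 (adjusted p = 0.0405, and adjusted p = 0.977 with an estimated correlation). The D493N arrays stood apart for some of these genes, and without D493N replicate 1 the log2 fold change was 0.42 for DnaJ-1, 0.31 for Hsp27 and -0.40 for Prosalpha4, while that of DnaJ-1 was 1.47 without D493N replicate 2. The call of DnaJ-1 was lost without control replicate 1 (adjusted p = 0.158) or 2 (0.0784), and those of Hsp27 (0.0765) and PEK (0.057, log2 fold change 0.36) without control replicate 1. With fry the heat-shock and detoxification calls were lost (adjusted p = 0.0516 each), and fat body markers were called lower (0.0468). Over all probe sets 1582 were higher and 1565 lower, 863 of them at least 2-fold. The count of 3147 became 1864 without control replicate 1 and 2003 without control replicate 2. That count was above those for wild-type EYA (2516) and E728Q (2648) in the single model of all arrays. With only the groups compared it was 2223 for D493N, below 3467 for wild-type EYA and 3296 for E728Q. The order of the groups by count therefore depends on which arrays enter the fit. The ER chaperone call was lost without D493N replicate 1 (adjusted p = 0.0768), with a range over the alternatives of 0.0042 to 0.977. The clock call was lost without control replicate 2 (adjusted p = 0.081), without D493N replicate 2 (0.0805) and without the genes of the chromosomal run (0.123), an alternative chosen after seeing the data, with a range of 0.00111 to 0.977.

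EYA E728Q against control asks the same of a transgene with little if any phosphatase activity. CG2444 (7.32), mthl8 (5.11), GstD9 (4.45), PGRP-SC2 (4.19), Nepl4 (4.05), CG14949 (4.05) and prc (4.02) had the largest increases. Eip63E, CG3706, CG3770, Ance-4 and CG2652 rose by 3.38 to 3.78 on the log2 scale. The largest decreases were in Tektin-C, a gene for a filament protein of sperm tails and cilia (-4.98, SE 0.46, adjusted p = 0.000108), phu (-4.70), CG42329 (-4.57), CG34217 (-4.03) and CG10513 (-4.01). CG5966, CG13315, CG6067, Obp99a, Prat2, Alp9 and Gart fell, with values from -3.57 to -2.67. Signals with E728Q were as low as 2.98 for CG42329 and 3.62 for CG34217, so sizes and ranks depend on the pseudocount. Over the alternatives log2 fold changes were -6.93 to -2.46 for CG42329, -6.17 to -2.05 for CG34217, -5.91 to -3.59 for Tektin-C and -5.16 to -1.16 for Alp9. For genes with low signals in control they were 3.05 to 6.93 for mthl8, 1.79 to 4.59 for CG2652 and 1.97 to 5.01 for CG3706.

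The proteasome and detoxification lists were called lower by camera with E728Q as well. Of 26 proteasome genes 22 fell and 0 rose (24 and 0 adjusted over the list alone), with Rpn11 at -0.57, Rpt2 at -0.54 and Rpn3 at -0.53. The proteasome list had adjusted p = 1.98e-08, and adjusted p = 0.991 with an estimated correlation, and the Act5C ratios of these arrays were 4.84 and 5.11. Of 44 detoxification genes 7 rose and 24 fell (8 and 27 adjusted over the list alone), with Ugt35C1 at -2.48 and Cyp4g1 at -2.22 (adjusted p = 0.000201, and adjusted p = 0.991 with an estimated correlation). Fat body markers were called lower beside them, 2 of 10 higher and 6 lower (2 and 7 adjusted over the list alone), with fit, a fat body gene expressed mostly in females, at -2.36, Cyp4g1 at -2.22, which both lists hold, fon at -1.57 and the storage protein gene Lsp2 at 1.60. Of 14 ER chaperones 7 rose and 0 fell (9 and 1 adjusted over the list alone), with CaBP1 at 0.61. Of 24 genes of the mitochondrial respiratory chain 5 rose and 0 fell (6 and 0 adjusted over the list alone), with RFeSP at 0.82 and SdhB at 0.66. Each of these last 3 lists had adjusted p = 0.0249, and adjusted p = 0.991 with an estimated correlation. With fry the detoxification and respiratory chain calls were lost (adjusted p = 0.064 and 0.21), and the clock was called higher (0.00327). Over all probe sets 1330 were higher and 1318 lower, 666 of them at least 2-fold. The count of 2648 became 1474 without control replicate 1, 1592 without control replicate 2, 1630 without E728Q replicate 1 and 1576 without E728Q replicate 2. With deposited values the adjusted p was 0.063 for ER chaperones, 0.411 for the respiratory chain and 0.0691 for fat body markers. The ER chaperone call was also lost without E728Q replicate 2 (adjusted p = 0.101), and the other calls without E728Q replicate 1 (0.178 for the respiratory chain and 0.0607 for fat body). Over the alternatives these adjusted p values lay between 0.0038 and 0.991.

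**Figure D2:**
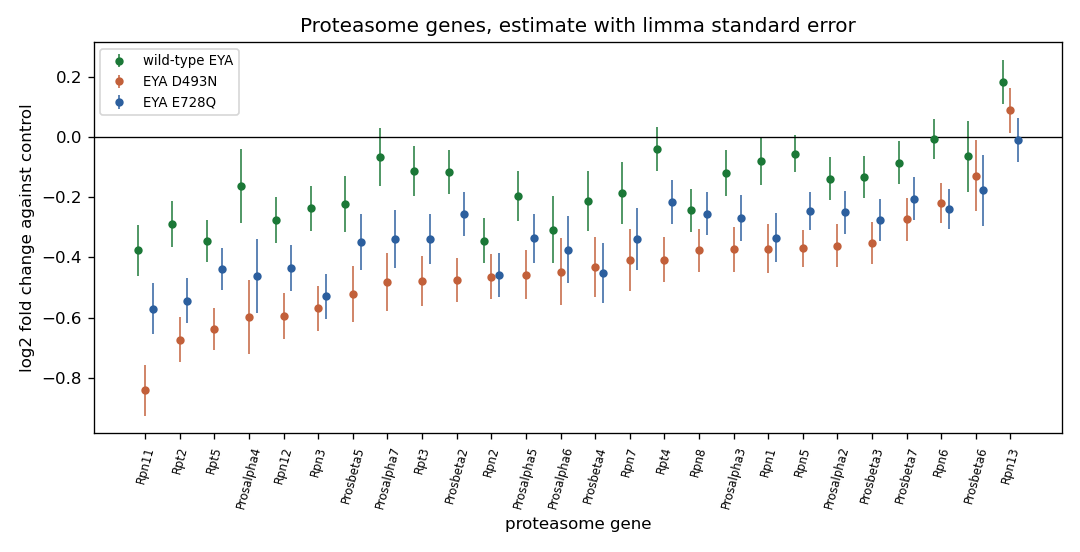
Log2 fold change against control of the 26 measured proteasome genes, with points for the estimates in each EYA group and bars for the limma standard error. Estimates lie below 0 for all genes with E728Q and for all but Rpn13 with D493N, and 25 of the 26 for wild-type EYA lie closer to 0 than either mutant.

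Few of the 23 measured eye specification genes were called against control. With wild-type EYA 2 rose, dpp (0.56) and gl (0.52). With D493N 2 rose, dpp (0.80) and gl (0.64), and 2 fell, pros (-0.67) and Pph13 (-0.35). With E728Q 2 rose, dpp (0.72) and lz (0.59). The counts adjusted over the list alone were 1 higher and 0 lower, 2 and 2, and 2 and 0, and the list was not called (adjusted p = 0.972, 0.971 and 0.862). For gl with D493N the value was 0.37 without D493N replicate 2. Without control replicates 1 and 2 in turn, calls were lost for gl with wild-type EYA (adjusted p = 0.163 and 0.128) and with D493N (0.0739 and 0.0585) and for Pph13 (0.0577 and 0.06), and that of lz was lost without control replicate 2 (0.0568). EYA's binding partner so had log2 fold changes of 0.38 (adjusted p = 0.0868), 0.28 (0.174) and 0.32 (0.134), and dac, also of the retinal network, 0.20 (0.457), 0.14 (0.587) and 0.01 (0.98). Of 26 phototransduction genes 4 rose and 4 fell with wild-type EYA, 4 and 5 with D493N, and 7 and 4 with E728Q (6 and 4, 5 and 5, and 9 and 4 adjusted over the list alone), with laza at 1.24, 1.34 and 1.20 and the carotenoid uptake gene ninaD at -0.88, -1.37 and -1.42 (list adjusted p = 0.51, 0.971 and 0.229). Of 22 eye pigment genes 3 rose and 5 fell, 3 and 5, and 5 and 5 (3 and 6, 3 and 5, and 5 and 5 adjusted over the list alone), with bw at 1.43, 1.76 and 1.55 and se at -1.74, -2.34 and -2.15 (list adjusted p = 0.559, 0.971 and 0.921). Of 5 photoreceptor markers 1 rose and 0 fell in each comparison (2, 1 and 2 higher adjusted over the list alone), namely gl in the wild-type and D493N groups and inaD (0.19) in the E728Q group (list adjusted p = 0.539, 0.956 and 0.446). The inaD call was lost without control replicates 1 and 2 (0.161 and 0.164), and that of ninaD with wild-type EYA without control replicate 1 (0.0941).

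The clock gene per rose by 2.02, 2.09 and 1.82 on the log2 scale with wild-type EYA, D493N and E728Q, and the clock regulator vri by 0.87, 0.98 and 1.08. In the list 6 clock genes were higher and 2 lower in the wild-type and E728Q groups (7 and 3 in each adjusted over the list alone; list adjusted p = 0.1 and 0.229). Heat-shock chaperones were not called with wild-type EYA, where 4 rose and 0 fell, with stv at 0.36, or with E728Q, where only Hsp26 (0.32) rose (4 and 1 higher adjusted over the list alone; list adjusted p = 0.0534 and 0.229). Of 14 ER chaperones only ERp60 (0.35) rose with wild-type EYA (also 1 adjusted over the list alone; list adjusted p = 0.16). Immune genes were not called with D493N, where 7 rose and 6 fell, or with E728Q, where 5 rose and 4 fell (8 and 6, and 8 and 5 adjusted over the list alone; list adjusted p = 0.369 and 0.446). The only measured Turandot gene, TotC, fell in each, with log2 fold changes of -1.82, -1.31 and -1.81. Among 23 cell cycle genes 4, 4 and 3 rose and 1, 2 and 2 fell (the same counts adjusted over the list alone), with the replication genes Mcm2 at 1.98, 2.53 and 1.93 and Orc1 at 1.32, 1.69 and 1.41 (list adjusted p = 0.209, 0.956 and 0.892). Among 16 apoptosis genes 3, 4 and 3 rose and 2, 2 and 4 fell (3 and 4, 4 and 3, and 3 and 4 adjusted over the list alone), with Debcl at 0.86, 0.98 and 0.87 and grnd at -1.07, -0.83 and -0.70 (list adjusted p = 0.889, 0.971 and 0.921). Egfr fell by 0.71, 0.87 and 0.69 on the log2 scale, among 23 EGF receptor and Ras genes of which 1, 1 and 2 rose and 1, 3 and 2 fell (1 and 1, 1 and 3, and 1 and 1 adjusted over the list alone; list adjusted p = 0.81, 0.971 and 0.921). Of 15 Notch pathway genes 3, 3 and 4 rose and 0, 3 and 1 fell (3 and 0, 5 and 3, and 5 and 2 adjusted over the list alone), with the Notch antagonist H at 1.31, 1.60 and 1.16 (list adjusted p = 0.51, 0.695 and 0.446). Without control replicate 1, calls were lost for stv (adjusted p = 0.103), ERp60 (0.0563) and Egfr (0.0914) with wild-type EYA, TotC (0.0752) with D493N, and Hsp26 (0.055), Egfr (0.0998) and grnd (0.0531) with E728Q, and without control replicate 2 for ERp60 (0.0711) and TotC (0.0618) in the same groups.

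Metabolic genes moved in both directions. Of 28 genes of lipid and carbohydrate metabolism 7, 6 and 5 rose and 12, 11 and 11 fell with wild-type EYA, D493N and E728Q (7 and 15, 7 and 13, and 7 and 12 adjusted over the list alone), with sug, a transcription factor of sugar sensing, at 2.25, 2.20 and 2.36 and the lipase gene Lip4 at -2.12, -1.82 and -1.91 (list adjusted p = 0.084, 0.285 and 0.229). Of 36 odorant-binding and antennal genes 7, 6 and 9 rose and 8, 7 and 9 fell (14 and 9, 7 and 9, and 12 and 9 adjusted over the list alone), with Obp99a at -2.88, -2.82 and -3.01 (list adjusted p = 0.51, 0.971 and 0.921). Arrays of a group stood apart for antennal genes singled out after their values were seen. Control replicates 1 and 2 had signals of 126 and 672 for Obp83b, 132 and 650.0 for Os-C, 21.6 and 203 for a5, and 65.3 and 223 for Obp19a, and D493N replicates 1 and 2 had 678 and 1546 for Obp83b. Ribosomal protein genes hardly moved, with 0, 1 and 1 of 29 higher and 1, 0 and 1 lower (0 and 0, 1 and 0, and 0 and 1 adjusted over the list alone), RpS21 being at -0.19 with wild-type EYA and -0.37 with E728Q and RpS12 at 0.23 with D493N (list adjusted p = 0.704, 0.695 and 0.999). Without control replicates 1 and 2 the calls of RpS21 with wild-type EYA (0.151 and 0.19) and of RpS12 (0.0592 and 0.0511) were lost. In the respiratory chain 2 genes rose and 0 fell with wild-type EYA, and 2 rose and 1 fell with D493N (2 and 0, and 1 and 0 adjusted over the list alone), with RFeSP at 0.58 and 0.41 (list adjusted p = 0.0555 and 0.971).

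Of the cell type markers, camera called only fat body with E728Q against control. That call was lost with an estimated correlation (adjusted p = 0.991) and with deposited values (0.0691). The other list test, fry, called fat body with E728Q (adjusted p = 0.0313) and with D493N (0.0468). Fat body markers showed 2 of 10 higher and 6 lower with wild-type EYA, and 2 higher and 5 lower with D493N (the same counts adjusted over the list alone; list adjusted p = 0.084 and 0.137), with fon at -0.98 and -1.53. Of 11 glial markers 1, 3 and 2 rose and 2, 5 and 2 fell with wild-type EYA, D493N and E728Q (the same counts adjusted over the list alone), with moody at 1.30, 1.35 and 1.15 and alrm at -0.79, -0.92 and -0.94 (list adjusted p = 0.557, 0.956 and 0.892). Of 14 neuronal markers 1, 0 and 1 rose and 1, 2 and 2 fell (0 and 0, 0 and 2, and 1 and 2 adjusted over the list alone), with the GABA receptor gene Rdl at -0.40, -0.70 and -0.77 (list adjusted p = 0.964, 0.956 and 0.921). None of 11 muscle markers and none of 7 testis and accessory gland markers was called by limma in any of the 3, over all probe sets or adjusted over the list alone (list adjusted p = 0.539, 0.577 and 0.974 for muscle, and 0.994, 0.956 and 0.921 for testis). Of 9 egg shell and germline markers only Cp19 (-0.83) passed with wild-type EYA and Cp18 (0.90) with D493N (only Cp19 adjusted over the list alone; list adjusted p = 0.901, 0.971 and 0.497). Of 9 midgut markers Jon66Ci rose (1.03 and 1.18) and Mal-A1 fell (-1.23 and -0.82) with wild-type EYA and D493N, Mal-A6 fell with D493N (-1.18), and 0 passed with E728Q (1 and 2, 1 and 2, and 0 and 0 adjusted over the list alone; list adjusted p = 0.606, 0.956 and 0.921). For Cp18 with D493N the value was 0.38 without D493N replicate 1 (adjusted p = 0.226) and 1.41 without D493N replicate 2, and for alrm with D493N it was -0.56 without D493N replicate 2. Without control replicates 1 and 2 in turn, calls were lost for Cp18 (0.149 and 0.173), Mal-A6 (0.159 and 0.188), and with wild-type EYA for Cp19 (0.0593 and 0.13), Rdl (0.162 and 0.128) and alrm (0.0919 and 0.116), and for alrm with E728Q (0.0518 and 0.0664). The calls of Jon66Ci were lost without control replicate 2 (0.182 and 0.0964), as was that of Mal-A1 with D493N (0.0502).

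The 3 comparisons with control shared most of their strongest genes. CG2444, mthl8, PGRP-SC2, GstD9, prc, CG14949, CG3706 and CG3770 were among the 12 largest increases in each, and phu, CG5966, CG10513, CG6067, CG13315, Prat2 and Obp99a among the 12 largest decreases in each. In total 940 probe sets were higher and 819 lower in all 3, where independent lists would share 21.3 and 20. Only 9 probe sets were called in opposite directions among the 3946 called in at least 1 comparison. Across probe sets, which are not independent replicates, log2 fold changes correlated with r = 0.863 between wild-type EYA and D493N, 0.866 between wild-type EYA and E728Q and 0.881 between the mutants, beside 0.5, 0.499 and 0.498 in 100 simulations of unchanged groups against the same controls. The covariances were 0.291, 0.267 and 0.297, beside 0.02 in each simulation set. The total of 1759 became 1015 without control replicate 1, 1078 without control replicate 2 and 1156 without wild-type replicate 1.

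The mean of the 3 EYA groups against control summarises what the transgenic flies share. Their Act5C ratios ran from 4.28 to 6.26, against 4.15 and 4.29 in control. PGRP-SC2 rose by 4.03 and GstD9 by 4.10 on the log2 scale, per by 1.98, bw by 1.58, and Prat2 and Obp99a had values of -2.98 and -2.90. Of 26 proteasome genes 23 fell and 0 rose (24 and 0 adjusted over the list alone; adjusted p = 2.32e-07), of 44 detoxification genes 27 fell and 8 rose (28 and 9 adjusted over the list alone; adjusted p = 0.00267), and of 14 ER chaperones 8 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0387). Each had an adjusted p = 0.991 with an estimated correlation. These lists were also called by fry, and 7 others by fry alone, with the clock at the lowest adjusted p (0.000856). In all, 1730 probe sets were higher and 1758 lower, 725 of them at least 2-fold. The count of 3488 became 1956 without control replicate 1 and 2068 without control replicate 2. The ER chaperone call was lost without control replicate 1 (adjusted p = 0.0661) or E728Q replicate 2 (0.0533) and with deposited values (0.076), with a range over the alternatives of 0.0104 to 0.991.

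Wild-type EYA against D493N sets the wild-type protein beside a mutant with reduced phosphatase activity. Comparisons between transgenes cannot separate the EYA form from the stock or insertion background of its flies. A run of neighbouring genes on chromosome arm 3R, with SPARC among them, was lower in the wild-type group, and whether that follows from EYA was left open. The Act5C ratios were 4.28 and 4.35 against 5.63 and 6.26. The laminin gene LanA (2.15, SE 0.17, adjusted p = 0.000719), the cytochrome P450 gene Cyp6a2 (1.76), CG34217 (1.65), CG18577 (1.54) and the RNA polymerase cofactor gene Ctr9 (1.41) were higher with wild-type EYA. Hsc70-2 (-2.89), CG31157 (-2.69), Achl (-1.69), the basement membrane gene SPARC (-1.33, SE 0.10, adjusted p = 0.000623) and CG30033 (-1.23) were lower. Over the alternatives, low signals gave log2 differences of -5.53 to -1.01 for CG31157 (signal 1.23 with wild-type EYA), -3.80 to -1.57 for Hsc70-2, 0.52 to 3.41 for CG34217 and 0.51 to 2.87 for CG18577, so their ranks depend on the pseudocount. SPARC signal was 2475 with wild-type EYA, 6673 with D493N and 7314 in control. All 26 proteasome genes had values above 0 with a median of 0.28. Only Rpn11 (0.46) passed over all probe sets, against 19 adjusted over the list alone. The proteasome list had adjusted p = 2.66e-16, and adjusted p = 0.924 with an estimated correlation. The respiratory chain (median 0.12, adjusted p = 5.66e-05), muscle markers (0.42, 0.00365) and odorant-binding genes (0.14, 0.0178) were called higher, and ER chaperones (-0.11) and ribosomal proteins (-0.05) lower (0.0252 each), all with adjusted p = 0.924 with an estimated correlation. Single genes passed in none of these lists but the odorant-binding genes Obp56a (0.98) and Obp57a (0.91), with 6 higher and 2 lower there and 0 in the other 4 lists adjusted over the list alone. All 6 calls were lost with fry (adjusted p from 0.0559 for the proteasome to 0.745 for muscle). Camera called none of the remaining lists (lowest adjusted p = 0.0961), and fry called eye pigment and clock genes lower (0.0178 each).

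In this comparison 70 probe sets were higher and 60 lower, 33 of them at least 2-fold. With deposited values 38 of 124 were higher, so the split between directions depends on the scaling. The count of 130 became 58 and 59 without control replicates 1 and 2, 17 and 21 without wild-type replicates 1 and 2, 242 and 1016 without D493N replicates 1 and 2, and 63 without either E728Q replicate. LanA, Cyp6a2, Ctr9 and SPARC were called under every alternative. The calls of CG34217, CG18577, Hsc70-2, CG31157, Achl and CG30033 were lost without wild-type replicate 1 (adjusted p = 0.256, 0.256, 0.256, 0.0831, 0.0584 and 0.173), and their adjusted p was at most 0.317 over the alternatives. CG34217 (0.142 and 0.14), CG18577 (0.117 and 0.117) and CG30033 (0.0819 and 0.0816) also lost their calls without control replicates 1 and 2. Without D493N replicate 1 the calls of ER chaperones (0.134), odorant-binding genes (0.177), ribosomal proteins (0.383), the respiratory chain (0.381) and muscle markers (0.785) were lost. ER chaperones and ribosomal proteins also lost theirs without wild-type replicate 2 (both 0.0748), ribosomal proteins without wild-type replicate 1 (0.0563), and the respiratory chain with deposited values (0.439). Over the alternatives these adjusted p values lay between 3.62e-11 and 0.924.

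Wild-type EYA against E728Q sets it beside the mutant with little if any phosphatase activity. The same run of genes was lower with wild-type EYA, and the Act5C ratios were 4.28 and 4.35 against 4.84 and 5.11. Tektin-C (4.06), CG42367 (2.71), CG42329 (2.22), LanA (2.05) and fit (1.74) were higher with wild-type EYA, and CG31157 (-2.28), SPARC (-1.36), the histone variant gene His2Av (-1.25), Achl (-1.17) and CG14252 (-1.17) were lower. SPARC, His2Av and CG14252 lie in the run. With low signals the log2 difference over the alternatives was 0.79 to 4.36 for CG42329, -5.03 to -0.78 for CG31157 and 2.74 to 4.99 for Tektin-C. All 26 proteasome genes had values above 0 with a median of 0.16, and 0 passed in limma over all probe sets or adjusted over the list alone (adjusted p = 2.3e-10, and adjusted p = 0.872 with an estimated correlation). Immune genes (0 passed, 4 higher adjusted over the list alone, adjusted p = 0.00586) and detoxification genes (Cyp6a2 at 1.49, also 1 adjusted over the list alone, adjusted p = 0.0454) were called higher, each with adjusted p = 0.872 with an estimated correlation. The 3 calls were lost with fry (adjusted p = 0.372 for the proteasome and 0.723 for the others). Camera called none of the remaining lists (lowest adjusted p = 0.0583), and fry called 0 lists. There were 40 probe sets higher and 40 lower, 31 of them at least 2-fold, and with deposited values 24 of 66 were higher. The count of 80 became 44 without either control replicate, 12 and 13 without wild-type replicates 1 and 2, 318 and 320 without D493N replicates 1 and 2, and 29 and 11 without E728Q replicates 1 and 2. It was 42 without the genes of the run, 230 with only the groups compared and 23 without the trend in the prior variance. More calls were lost without the run than the 13 genes of it called lower against both mutants. The adjusted p of the probe sets that stayed in changes as well. LanA and SPARC were called under every alternative. Without wild-type replicate 1 the adjusted p was 0.0999 for Tektin-C, 0.261 for CG42367, 0.0829 for CG42329, 0.085 for fit, 0.183 for CG31157, 0.153 for His2Av and 0.261 for Achl, and without wild-type replicate 2 it was 0.087 for CG14252. The highest over the alternatives of these genes was 0.261, and CG42367 also lost its call without control replicates 1 and 2 (0.0752 and 0.0744). The immune call was lost without E728Q replicate 1 (0.0548), and the detoxification call without control replicates 1 and 2 (0.0569 and 0.057), wild-type replicate 1 (0.247) or E728Q replicate 1 (0.622), with ranges over the alternatives between 0.000144 and 0.872.

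EYA D493N against E728Q compares the mutants, whose Act5C ratios were 5.63 and 6.26 against 4.84 and 5.11. Tektin-C (4.12), CG42329 (2.73), CG34134 (1.46), CG33296 (1.44) and the prenyltransferase gene heix (0.90) were higher with D493N, and the detoxification genes Cyp28a5 (-1.14), Ugt35C1 (-1.03) and Cyp6g1 (-0.97), CG14275 (-0.81) and Sod3 (-0.71) were lower. Over the alternatives the values were 1.09 to 4.96 for CG42329 and 2.79 to 5.05 for Tektin-C, whose signals are low with E728Q. Sod3 has another probe set that rose against control by 3.19, 1.54 and 2.09 on the log2 scale with wild-type EYA, D493N and E728Q, where the brighter one had values of -0.59, -1.01 and -0.30, so the gene's probe sets disagree. The respiratory chain was called lower with D493N (median -0.13, SdhB at -0.58, 0 higher and 2 lower adjusted over the list alone, adjusted p = 4.7e-08), as were the proteasome (-0.12, 0.00189) and phototransduction genes (-0.06, 0.0437), and heat-shock chaperones were called higher (0.08, 0.0437). In these last 3 lists limma called 0 genes over all probe sets and 2 heat-shock chaperones adjusted over the list alone, and each of the 4 lists had adjusted p = 0.856 with an estimated correlation. The 4 calls were lost with fry (adjusted p = 0.729 each). Camera called none of the remaining lists (lowest adjusted p = 0.0644), and fry called 0 lists. There were 10 probe sets higher and 9 lower, 9 of them at least 2-fold, and 1476 had an unadjusted p under 0.05. The count of 19 became 63 and 1101 without D493N replicates 1 and 2, and 10 and 4 without E728Q replicates 1 and 2. Without E728Q replicate 2 the adjusted p was 0.13 for CG34134, 0.0894 for CG33296, 0.119 for Ugt35C1, 0.211 for Sod3, and 0.0768 for heix, Cyp28a5, Cyp6g1 and CG14275. Sod3 also lost its call without control replicates 1 and 2 (0.115 and 0.114) and wild-type replicates 1 and 2 (0.114 and 0.112). Each of the 10 named genes lost its call with only the groups compared, with adjusted p of at most 0.393 over the alternatives. Phototransduction and heat-shock calls were lost without control replicates 1 and 2 (0.0588 and 0.0586), wild-type replicates 1 and 2 (0.0534 and 0.0535), D493N replicate 1 (0.511) or E728Q replicate 1 (0.0691), and without E728Q replicate 2 (0.0867 and 0.0934). The phototransduction call was lost with deposited values as well (0.366), and over the alternatives these adjusted p values lay between 6.21e-05 and 0.856.

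Responses specific to wild-type EYA were those called against control and against both mutants in the same direction. No EYA form was measured in another stock, so they cannot be told apart from the stock or insertion background of the wild-type EYA flies. Of 31 such probe sets 8 were higher, among them LanA (log2 fold change of 1.61 against control), CG12105 (3.81) and Cyp6a2 (1.24), and 23 were lower, among them SPARC (-1.44), Achl (-2.08), CG14252 (-1.47) and His2Av (signal 1006 with wild-type EYA against 2080.0 in control). Others, chosen after their values were seen, were Obp57a (1.30), vib (0.40) and CHKov1 (0.35) among the higher, and the immune receptor gene Tl (-1.03), the polarity gene scrib (-0.86 and -0.90 for its 2 probe sets), Idgf3 (-1.75) and Tsp97E (-1.24) among the lower. The rule does not ask that the mutants match the control, and for some genes part of the change was shared. Signals in control, wild-type EYA, D493N and E728Q were 123, 1875, 1192 and 1311 for CG12105 and 3910, 1092, 1971 and 1836 for Idgf3. One of 2 probe sets of gol, also chosen after its values were seen, went from 14.1 and 2.89 in control to 1753 and 1686 with wild-type EYA and was at most 16.1 on the mutant arrays, while the brighter one had a log2 fold change of 0.34 (adjusted p = 0.169). Of 25 genes lower against both mutants, 13 lie in a run of neighbouring genes on chromosome arm 3R that includes SPARC, His2Av, Tl and scrib, and of 14 genes higher against both, 0 do. The run was drawn from the same difference between wild-type EYA and the mutants, so these counts follow in part from how it was chosen. The alternative without the run left out only the brightest probe set of each gene, so 1 of the 2 for scrib stayed in. It also changed the adjusted p of the other probe sets, so a fall in count there is not the number of calls in the run. The count of 31 became 16 without the genes of that run, 20 and 19 without control replicates 1 and 2, 6 and 8 without wild-type replicates 1 and 2, 59 and 63 without D493N replicates 1 and 2, and 15 and 6 without E728Q replicates 1 and 2.

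**Figure D3:**
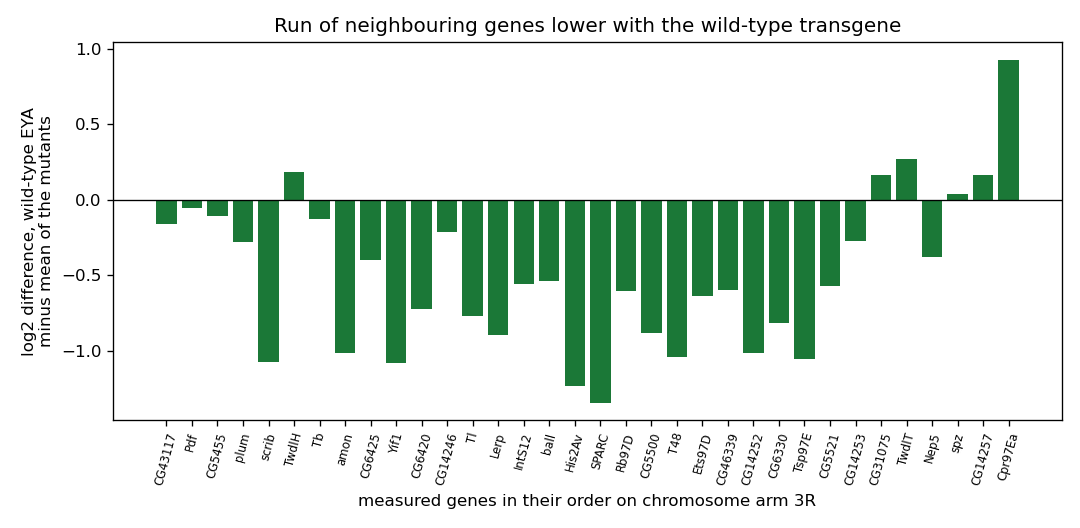
Log2 difference between wild-type EYA and the mean of the mutants (vertical axis) for the 34 measured genes of the run on chromosome arm 3R, as bars in their order along the arm. Of these genes 28 are lower with wild-type EYA.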

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

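The control probe set AFFX-Dm-K01486-1_at was outside the tests and gave a signal on the EYA arrays far above that of the controls. Its lowest signal on the 6 EYA arrays was 734.3, where the highest of the 2 control arrays was 14.05. Group means were 8.13 in control, 1634 with wild-type EYA, 3685 ± 2586 (SD, n = 2) with D493N and 796 with E728Q. Which transcript this probe set detects is not given in the sources used here, so whether the signal is of the driver itself or of a fly gene was left open.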

How the results depend on the processing

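The test without the genes of the chromosomal run was chosen only after the result was seen. Of 321 named gene results that were called, 200 were called under every alternative run, 612 of 5723 alternatives lost a call, and 0 changed direction. The list calls were kept in 485 alternatives and lost in 124, and 0 turned direction. With only the groups compared, the number of probe sets was 17 for wild-type EYA against D493N, 230 against E728Q, 3 between the mutants and 10 for the wild-type-specific set, and without the trend in the prior variance 27, 23, 7 and 10. A replicate block gave 86 for wild-type EYA against D493N and 46 against E728Q. Same-number deviations over all tested probe sets correlated across groups at only -0.144 to 0.094. That shows no broad pairing by number, but it cannot exclude a shared day that moved a part of the genes. No filter gave 46 for wild-type EYA against E728Q, and leaving out the genes of the run gave 42 there and 16 for the wild-type-specific set. These falls include calls of probe sets that stayed in the test. An estimated correlation left 0 of 29 list calls, with a lowest adjusted p of 0.856 over all lists and comparisons, so its losses do not tell the lists apart. The test fry kept 9 of the 29 and called 14 other lists. Except where fewer samples were used, the cause was not tested. Leaving out 1 array gave 1409 to 3419 for wild-type EYA against control, 1864 to 3728 for D493N, 1474 to 3518 for E728Q, 1956 to 4344 for the mean of the 3, 1015 to 2163 shared, 17 to 1016 for wild-type EYA against D493N, 11 to 320 against E728Q, 4 to 1101 between the mutants, 6 to 63 wild-type-specific and 24 to 43 list calls. With deposited values the share of higher probe sets went from 53.8% to 30.6% for wild-type EYA against D493N, from 50% to 36.4% against E728Q and from 52.6% to 68.8% between the mutants.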

Other observations

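Several enzymes of purine and folate metabolism, chosen after their values were seen and not tested for enrichment, moved with all 3 transgenes. With wild-type EYA, D493N and E728Q, log2 fold changes against control were -2.93, -3.14 and -2.87 for Prat2, -2.82, -2.73 and -2.67 for Gart, and -3.03, -2.56 and -2.42 for Nmdmc. Paics (-0.97, -1.11 and -0.79), Pfas (-0.69, -1.03 and -0.90) and Shmt (adjusted p = 0.000922, 0.00112 and 0.000699) fell as well. Prat, which encodes the same activity as Prat2, rose (1.34, 1.52 and 1.07), as did Adk3 (2.54, 2.03 and 1.97), Mthfs (1.90, 2.46 and 2.04) and Aprt (0.60, 1.67 and 1.41), while pug was at 0.29, 0.22 and 0.30 and was not called.

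The EYA groups differed from control in a shared way, and the tests of the shared control arrays and of the driver or stock background were chosen only after the result was seen. Chance values that arise in each control array on its own are argued against, since the smallest covariance of a pair of comparisons, 0.267, lay above the highest simulated value, 0.0221. The simulations varied each array independently, so they do not cover a shift common to both control arrays, such as from a shared fly culture. Quantile normalization is argued against as well, since 1595 probe sets were called in all 3 comparisons with deposited values, 1546 of them among the 1759. What also stays open is the driver, stock or insertion background, which differs between w1118 and the transgenic flies and cannot be told apart from EYA, because 0 of the 4 groups carry the driver without an eya transgene. The responses may therefore be to EYA or to that background, or reflect a shift common to the control arrays.

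Wild-type EYA flies had lower signals over a run of neighbouring genes on 3R from CG43117 to Cpr97Ea, in the order of the assembly Release 6 plus ISO1 MT, and the test of a single gene copy was chosen only after the result was seen. The run was noticed by inspection and then scanned (largest window median -0.82, permutation p = 0.005, the smallest that 200 permutations can give). Quantile normalization and a bias with signal level are argued against, since the median against the mean of the mutants was -0.589 with deposited values and genes of the same signal level did not show the difference (lowest median of 10000 matched random lists -0.144), although that 0 of them were as low as the run follows in part from how the run was found. A candidate explanation is a single copy of these genes in place of a pair, which cannot be told apart from an effect of EYA. The median over 34 measured genes was -0.565 with 82.4% lower against the mean of the mutants, short of the -0.7 set for a single copy but not above the -0.5 set against it, and -0.435 with 22 of 34 lower against control, a comparison for which no bound was set. The ends of the run were set by whole windows of 15 genes, so it takes in end genes such as Pdf (-0.05) and Cpr97Ea (0.93). Its median depends on where the ends are drawn. The window of -0.82, from CG14246 to Tsp97E, lies past the -0.7 but was chosen as the largest, so these medians do not decide.

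Proteasome genes were lower in the phosphatase mutants, and all tests here were chosen before their results were seen. Quantile normalization is argued against, since the medians were -0.407 for D493N and -0.324 for E728Q with deposited values, beside -0.439 and -0.337. So is a bias with signal level, since 0 of 10000 and 0 of 10000 matched random lists had medians as low, the lowest being -0.261 and -0.2. RNA quality stays open, since with the Act5C ratio as a covariate the medians were -0.292 (mean SE of the single genes 0.317) and -0.255 (0.168), and the ratio follows the groups, so it cannot be told apart from the mutations. The ratio of 3' to 5' signal for eIF4a was 2.51 and 2.73 in control and 3.02 and 4.05 with D493N. The other groups had another order than for Act5C, with 2.89 and 3.23 for wild-type EYA and 2.8 and 2.87 for E728Q. For GAPDH it was 1.72 and 1.78 in control and 2.05 and 2.05 with D493N. With wild-type EYA the GAPDH ratio was 1.97 and 1.72, and with E728Q 1.94 and 2.03. For all of these controls the group mean was highest with D493N and lowest in control. Neither eIF4a nor GAPDH was used as a covariate. The fall may be linked to RNA quality, to the driver, stock or insertion background or to lost phosphatase activity, which was not tested. It does not follow the order of activity, as D493N keeps more activity and fell further than E728Q (list adjusted p = 0.00189 between them with camera, 0.856 with an estimated correlation and 0.729 with fry). The gap between the mutants cannot be told apart from their RNA quality, so this order does not decide. With wild-type EYA 25 of 26 proteasome genes also had values below 0 (list adjusted p = 0.0116, and 0.942 with an estimated correlation).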
